A study of Homo sapiens with 43 samples.

How the data were processed

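RNA was isolated from quadriceps biopsies and sequenced in paired-end reads on an Illumina instrument, per the labels' protocols. The values deposited by the authors are estimated counts of reads per Ensembl gene, not scaled to library size, with 1 column for each of the 43 libraries. Per the submitters' processing notes STAR, Partek and DESeq2 were used with GRCh38 (hg38), and their versions, the settings of the counting step and the annotation release are not given in the sources used here. The unit was checked on the values: none is negative, and between 39.0% and 84.3% of the values in a column, zeros included, are whole, with a tolerance of 0. The table has 24052 genes, of which 19749 carry a symbol in the table, 5 took one from a gene name table and 4298 kept their Ensembl identifier. Among these, 75 genes had no annotation in the table and held at most 0.251% of a library's counts, and they were kept. Gene positions are those of the table, 1-based, with the stop shifted by 1 to the last base of the gene.

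Groups were taken from the labels. Libraries were paired by the participant code that the library names share, so the pairing rests on samples coming from the same donor. The correlation of deviations from the group means had a median of 0.366 for libraries of the same participant and -0.0357 for others between injured and healthy muscle, 0.158 and 0.00292 between post-Sx and healthy, and 0.183 and 0.0208 between post-Sx and injured. In the same order, the closest match of a library in the other group was its own participant's in 8 of 16, 3 of 10 and 4 of 10 pairs. The lowest correlations within a participant were -0.230, -0.327 and -0.396. Sex-linked transcripts disagreed between libraries of the same person in 0 of 16 participants. No 2 libraries of a group looked like copies of each other, with a smallest chi-square per degree of freedom of 36.0 within a group.

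Estimated counts were rounded to whole numbers for the tests. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), scaled with TMM factors and tested with edgeR 4.0.16 in R 4.3.3, by a robust quasi-likelihood F test with the participant as a block, on 42 libraries of 16 participants in 1 fit. A healthy library of a further participant, with no second library, entered only the fits with no replicate block and the fit with the participant as a random effect. P-values were adjusted by the Benjamini-Hochberg method at a false discovery rate of 0.05. CPM were computed from the counts with TMM factors, and log2 CPM used a prior count of 2.

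The comparisons, the tests, the 41 gene lists, the rule for naming genes and a set of alternatives were written before the data were examined. Named genes are 16 fixed core genes, the 8 largest rises and 8 largest falls among genes that passed, had a mean of at least 1 CPM and moved the same way in at least 75% of pairs, and up to 4 members per list with the smallest p among those that passed, or the 1 with the smallest p where none passed. Y-linked genes, XIST, immunoglobulin and T cell receptor segments and genes with no symbol were left out of the largest rises and falls, but not of the members of a list. Of the core genes DACH2 is not in the table, and 1 gene that the rule selects is not reported here. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated correlation, and with fry, with adjustment over the lists of a comparison.

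Alternatives set in advance were a fit with no replicate block, the participant as a random effect in limma-voom, DESeq2 1.42.0, RLE and upper-quartile scaling, no filter and a stricter filter (1 CPM in at least 10 libraries), only the groups compared, only the 10 participants with 3 libraries, leaving out name prefixes, suffixes or single participants, and a minimum change of 1.5-fold. Chosen after seeing the data were the fits without the 2 or the 4 libraries with the fewest genes detected, without both participants of the former, with genes detected, the first principal component or the TMM factor as a covariate, with sample quality weights, with limma-voom and a replicate block, and with trends over transcript length or GC content removed (GENCODE transcripts for 99.0% of the tested genes; lowess, span 0.3).

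The correlation of the changes in the injured and post-Sx groups was set beside 100 simulations of unchanged groups. A first version kept the real healthy libraries around their fitted means, where their residuals sum to 0 over participants, so that it removed the covariance from a shared control that it was to measure. It had put the observed covariance above every simulated one. It was replaced, after that outcome was seen, by resampling the residuals of all libraries, and the observed covariance then lay inside the simulated range. Label swaps within participants were drawn 22 times per comparison, the real labels included, and splits of the participants by prefix 24 times. For the 6 participants without a post-Sx library all 64 swaps were run, a test added after the correlations had been seen. Correlations over libraries used 100000 permutations.

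The tests were tested on simulated data with 200 changed genes per comparison. In the simulation of injured against healthy muscle 5 unchanged genes were called, in that of post-Sx against healthy 1 and in that of post-Sx against injured 5. Of the changed genes in the last of these, 4.62% were recovered at 1.5-fold, 47.7% at 2-fold and 89.2% at 4-fold.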

Results

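Gene expression was measured by RNA sequencing of quadriceps muscle biopsies from people with an injury of the anterior cruciate ligament (ACL), the ligament that stabilises the knee. The 43 libraries fell into 3 groups: 17 from the limb without the injury (called healthy here, as in the study's design text), 16 from the injured limb, and 10 taken 7 days after an event that the labels shorten to Sx (called post-Sx here). The labels do not state the limb of the post-Sx biopsies in words. Library names carry the code NR for the non-injured limb, R for the injured limb and R2 for post-Sx. The code R2 thus points to the injured limb, but its meaning is not given. The libraries came from 17 participants. For 16 of them at least 2 libraries were held, and these 42 libraries entered the paired tests, with 16 pairs for injured against healthy and 10 pairs for each comparison with post-Sx muscle. The total of estimated counts per library ranged from 16659385 to 56986593, with a median of 19657987, and between 13616 and 22715 genes had a count above 0. After the filter on low counts, 16252 genes were tested. The healthy and injured libraries were reused from an earlier series, per the study's design text. The post-Sx libraries may thus form a sequencing batch of their own, and in the paired tests this batch and the post-Sx group cannot be told apart. The title of healthy 17, which entered no paired test, differs in form from those of the other healthy libraries.

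The first comparison named in the study's design asked how the injured limb differed from the other limb of the same person. HDAC4, a class IIa histone deacetylase whose induction in denervated muscle is well known, averaged 30.26 ± 15.99 CPM (library-scaled counts; SD, n = 16) in healthy and 61.1 ± 35.6 CPM (SD, n = 16) in injured muscle, a log2 fold change of 0.94 (SE 0.26) with the injured limb higher in 12 of 16 pairs. CHRNA1, the alpha subunit of the muscle acetylcholine receptor, had a log2 fold change of 1.30 (SE 0.34; 12 of 16 pairs higher). RUNX1, a transcription factor of denervated fibres, stood at 1.19 (SE 0.34; 12 of 16 pairs higher). These 3 genes each had an unadjusted p under 0.05 and an adjusted p of 0.817 with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, so that none passed over all genes tested. Across the transcriptome 0 genes passed. An unadjusted p under 0.05 was found for 740 genes (312 higher and 428 lower), against 812.6 expected by chance. On simulated data of this comparison, the same test recovered 25.8% of genes changed 1.5-fold, 64.6% of those changed 2-fold and 98.4% of those changed 4-fold.

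2 other tools passed a few genes for the injured limb. DESeq2 called 8 genes, 2 higher and 6 lower: CHRNA1 (log2 fold change 1.32) and PADI2 (0.67) were higher, while RASL12 (-0.86), NR4A1 (-0.85), DUSP10 (-0.77), SNAI3 (-1.02), LDAF1 (-0.70) and TLCD3B (-1.47) were lower, with adjusted p from 0.0458 to 0.0499. A limma-voom fit with sample quality weights called 1 gene, HABP2 (-1.66, adjusted p 0.0346). Apart from CHRNA1, NR4A1 and TLCD3B these genes fell outside the rule for named genes and were chosen after their values were seen. All other fits and tools called 0 genes, except a fit of only the 3 pairs with a name suffix b, which called 5.

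By gene list, the denervation response list was the one with the largest share of members in one direction among those that rose in the injured limb by the preset-correlation test: 19 of its 22 tested members had a positive log2 fold change, with a median of 0.49. Adjusted over the list alone, 4 members were higher in injured muscle, namely CHRNA1, HDAC4, RUNX1 and CHRND, against 0 over all genes tested. The camera test with a preset correlation of 0.01 gave an adjusted p of 4.37e-09, and an adjusted p = 0.195 with an estimated correlation. The neuromuscular junction list (1 higher, CHRNA1), the class IIa deacetylase and MEF2 list (1 higher, HDAC4), the insulin-like growth factor and mTOR list (1 higher, the stress-induced SESN3 at 0.82), the circadian clock list (1 higher, TEF at 0.43, positive in 16 of 16 pairs) and the immediate early gene list (2 lower, NR4A1 at -0.87 and NR4A3 at -1.51) were the others with any member passing adjusted over the list alone. Oxidative phosphorylation had 1 of 55 members positive (median -0.24; camera adjusted p 9.17e-10, adjusted p = 0.553 with an estimated correlation). Glycolysis and glycogen had 2 of 30 (median -0.22; 4.37e-09, adjusted p = 0.269 with an estimated correlation). The 3 lists with the lowest medians were markers of cell types. Erythrocyte markers had 0 of 5 positive (median -1.93; camera adjusted p 6.75e-06, adjusted p = 0.269 with an estimated correlation). Neutrophil markers had 0 of 9 (median -0.90; 0.00302, adjusted p = 0.558 with an estimated correlation). Adipocyte markers had 1 of 15 (median -0.78; 1.002e-06, adjusted p = 0.269 with an estimated correlation). With no replicate block the medians were -0.52 for erythrocyte, -0.25 for neutrophil and -0.67 for adipocyte markers. In all, camera with the preset correlation called 15 of the 41 lists, 4 of them upwards, 0 of the 41 with an estimated correlation, and fry, which tests whether a list moves one way on balance, called 0.

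The second comparison named in the design set muscle 7 days post-Sx against the healthy limb. Genes of the denervation response formed the group with the highest median: 14 of 22 tested members rose and 1 fell, with a median log2 fold change of 1.97. CHRNA1 went from 13.7 ± 8.47 CPM (SD, n = 16) in healthy muscle to 298 ± 120 CPM (SD, n = 10) post-Sx, a log2 fold change of 4.19 (SE 0.41, adjusted p 4.09e-08, higher in 10 of 10 pairs). MYOG, the myogenic transcription factor that activates acetylcholine receptor genes, rose by 2.55 (SE 0.27, adjusted p 1.44e-07, 10 of 10), from 66.2 ± 25.1 to 398 ± 227 CPM. RUNX1 rose by 3.19 (SE 0.40, adjusted p 1.15e-06, 10 of 10). HDAC4 reached 125 ± 38.1 CPM (SD, n = 10), a log2 fold change of 2.21 (SE 0.31, adjusted p 5.17e-06, 10 of 10).

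The gene-level positions are given in GRCh38, the build named in the submitters' processing notes, for the genes this comparison rests on. HDAC4 (ENSG00000068024) lies on chromosome 2 at 239048168 to 239401654, CHRNA1 (ENSG00000138435) on chromosome 2 at 174747592 to 174787935, MYOG (ENSG00000122180) on chromosome 1 at 203083129 to 203086012, RUNX1 (ENSG00000159216) on chromosome 21 at 34787801 to 36004667 and ACTN3 (ENSG00000248746) on chromosome 11 at 66546395 to 66563334. All are annotated as protein-coding genes, and the counts are per gene over its transcripts.

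Over the whole transcriptome 3542 genes passed in this comparison, 1702 higher and 1840 lower post-Sx, of which 531 and 1125 changed at least 2-fold. The test was edgeR's quasi-likelihood test with the participant as a block, in the joint fit of 42 libraries, with 10 pairs of these 2 groups. With only the 10 participants with 3 libraries 2794 genes were called, and with only these 2 groups in the fit 2868. The fit with no replicate block, over all 43 libraries, called 3636 genes. With upper-quartile scaling the split was 1336 higher and 2171 lower, so that the share of higher calls went from 48.1% to 38.1%. Sample quality weights raised the count to 6264 genes, the first principal component as a covariate to 5653 and the TMM factor as a covariate to 7394. On simulated data of this comparison only 200 genes were changed, far fewer than were called here. There 5.97% of genes changed 1.5-fold, 49.3% of those changed 2-fold and 92.2% of those changed 4-fold were recovered.

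**Figure D1:**
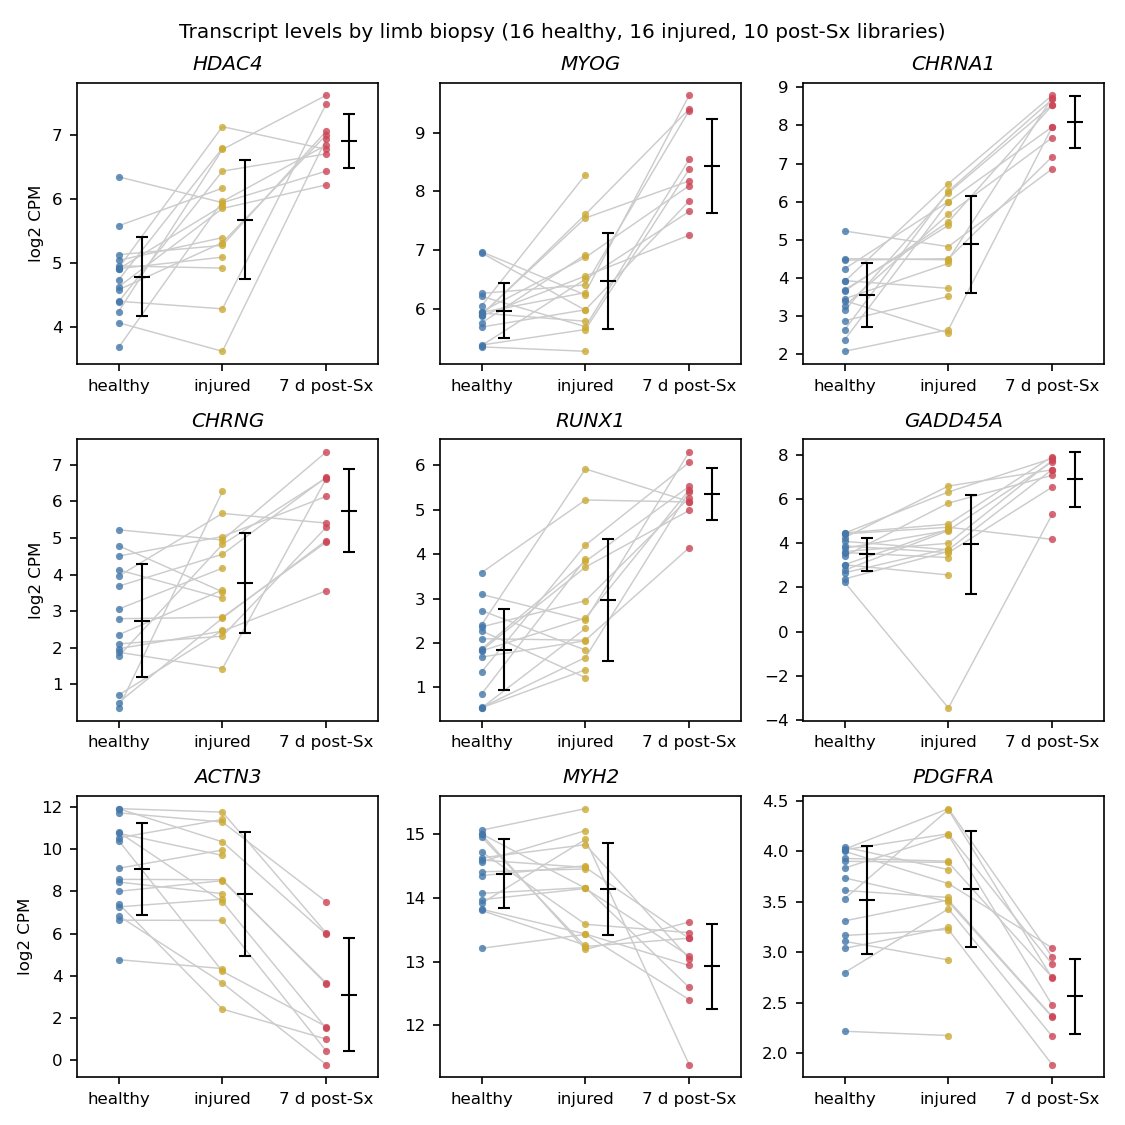
Transcript levels of 9 genes in log2 CPM (vertical axes) in healthy (n = 16), injured (n = 16) and 7-day post-Sx (n = 10) muscle; each point is a library, grey lines join libraries of one participant, and black marks give the mean and SD of the group. HDAC4, MYOG, CHRNA1, CHRNG and RUNX1 were higher post-Sx than in healthy muscle in 10 of 10 pairs, and ACTN3, MYH2 and PDGFRA were lower in 10 of 10.

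Of the subunits of the muscle acetylcholine receptor, some of them members of this list, all rose but CHRNE, which did not pass. No difference between subunits was tested. CHRNG, the fetal gamma subunit, rose by 2.96 (SE 0.44, adjusted p 1.39e-05), CHRND by 2.20 (SE 0.36, adjusted p 4.10e-05) and CHRNB1 by 1.20 (adjusted p 2.08e-05), while CHRNE, the adult epsilon subunit, had a log2 fold change of -0.21 (SE 0.46, adjusted p 0.815). In the neuromuscular junction list 11 of 35 members rose and 3 fell (median 0.13; camera adjusted p 0.0868). The receptor tyrosine kinase MUSK stood at 1.11 (SE 0.45, adjusted p 0.0742) and the adhesion molecule NCAM1, which is known as a marker of denervated fibres, at -0.82 (SE 0.34, adjusted p 0.0841), and neither passed. GADD45A, a stress-induced gene downstream of HDAC4 in denervated mouse muscle, rose by 3.20 (SE 0.41, adjusted p 1.85e-06). In the class IIa deacetylase and MEF2 list 4 of 19 members rose and 4 fell (median -0.03): HDAC9 fell by 1.84 (SE 0.51, adjusted p 0.00929), HDAC7 by 0.50 and the kinase CAMK2A by 1.44, and HDAC5 stood at -0.23 (SE 0.28, adjusted p 0.626).

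Lists of contractile and metabolic genes of the fibre had more falls than rises post-Sx. Of the fast fibre contractile list 11 of 19 members fell and 1 rose (median -1.03; camera adjusted p 5.25e-09, adjusted p = 0.0835 with an estimated correlation): ACTN3, the alpha-actinin of fast fibres, fell by 6.15 (SE 0.64, adjusted p 8.82e-08), ATP2A1, the fast calcium pump, by 2.61, and the calcium-binding CASQ1 by 1.72. The myosin heavy chain MYH2, outside the rule for named genes and chosen after its values were seen, fell by 1.27. Of the slow fibre contractile list 10 of 18 fell and 0 rose (median -1.17; 4.95e-08, adjusted p = 0.151 with an estimated correlation), with MYH7B at -2.45 and MYL3 at -3.24. Glycolysis and glycogen genes were the metabolic list with the most falls, 22 of 30 with 1 rise (median -0.99; 2.66e-13, adjusted p = 0.0436 with an estimated correlation), among them FBP2 (-4.23), the glycogen phosphorylase PYGM (-1.48) and PHKG1 (-2.13). In oxidative phosphorylation 8 of 55 members fell and 0 rose (median -0.38; 0.000297, adjusted p = 0.656 with an estimated correlation), and without the 2 libraries with the fewest genes detected 23 fell. Fatty acid oxidation and mitochondrial biogenesis had 10 falls and 1 rise among 36 (median -0.33; 0.00602, adjusted p = 0.409 with an estimated correlation), including IDH2 (-1.04) and FABP3 (-1.35). Excitation-contraction coupling and channel genes had 6 falls and 1 rise among 22 (median -0.49; 0.00224, adjusted p = 0.0835 with an estimated correlation), with the junctophilin JPH2 at -1.47.

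Lists of protein turnover and of ribosome assembly were tested as well. Among 32 proteasome subunits 17 rose and 0 fell (median 0.62; camera adjusted p 4.90e-09, adjusted p = 0.250 with an estimated correlation), with PSMD11 at 0.82 (adjusted p 1.02e-05). Among 25 autophagy and lysosome genes 10 rose and 0 fell (median 0.34; 0.00449, adjusted p = 0.135 with an estimated correlation), with the autophagy receptor SQSTM1 at 1.27 and BNIP3L at 0.92. Ribosome biogenesis had 13 rises and 0 falls among 25 (median 0.63; 5.37e-07, adjusted p = 0.0427 with an estimated correlation), with BYSL at 0.96 and NOB1 at 0.88, whereas 1 of 49 cytosolic ribosomal protein genes rose (RPL12, 0.85) and 0 fell. The atrophy and ubiquitin ligase list was divided, with 3 rises and 4 falls among 24 (median -0.02). FBXO32 (atrogin-1) and TRIM63 (MuRF1), the ubiquitin ligases most used as markers of atrophy, had log2 fold changes of -0.04 (SE 0.22, adjusted p 0.932) and 0.01 (SE 0.27, adjusted p 0.988), FBXO40 fell by 1.63 and FOXO1 rose by 0.76.

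Marker lists of connective tissue cells and of macrophages had more falls than rises post-Sx, while that of endothelium showed 0 rises and 1 fall among 17 (median 0.02). In the fibro-adipogenic progenitor list 17 of 20 members fell and 0 rose (median -1.40; camera adjusted p 5.51e-11, adjusted p = 0.0427 with an estimated correlation): PDGFRA, the receptor that marks these cells, fell by 1.14 (SE 0.12, adjusted p 9.96e-08, lower in 10 of 10 pairs), MFAP5 by 4.02 and DPT by 1.84. Of 50 extracellular matrix genes 31 fell and 1 rose (median -1.05; 1.34e-16, adjusted p = 0.0835 with an estimated correlation), with FBLN1 at -1.52 and TIMP2 at -1.33. Of 7 tenocyte markers 5 fell and 0 rose (median -1.57; 0.00170, adjusted p = 0.135 with an estimated correlation). Of 22 macrophage and monocyte markers 12 fell and 0 rose (median -1.15; 1.42e-05, adjusted p = 0.299 with an estimated correlation), with LYVE1 at -3.08 and C1QC at -1.53. Of 15 adipocyte markers 8 fell and 1 rose (median -1.61; 0.000714, adjusted p = 0.348 with an estimated correlation), with ADIPOQ at -4.02; the member that rose, SAA1, is an acute-phase gene.

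The other marker lists gave 1 to 8 calls each. Pericyte and smooth muscle markers had 3 falls among 15 (LMOD1, -2.17), T and NK lymphocyte markers 1 fall among 15 (CD4, -1.62), and B and plasma cell markers 1 rise among 6 (XBP1, 0.67). Neutrophil markers had 2 rises among 9 (S100A8 at 2.01 and S100A9 at 1.81), erythrocyte markers 1 rise among 5 (ALAS2, 2.17), and Schwann cell and nerve markers 2 rises and 3 falls among 11 (ERBB3 at 2.14, S100B at -2.54). Satellite cell markers had 3 rises and 1 fall among 20, with PAX3 at 1.74 and PAX7 at -0.58. The cell cycle list had 1 fall among 14 (AURKA, -1.16), and the embryonic and regenerating fibre list 5 rises and 3 falls among 19, with MYOD1 at 1.76 and VIM at -1.46.

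Signalling lists were divided between rises and falls. Myostatin, activin and TGF-beta had 4 rises and 7 falls among 32, with the ligand TGFB3 at 1.75, the antagonist FST at 1.91 and LTBP4 at -1.75. Insulin-like growth factor and mTOR had 4 rises and 6 falls among 25, with IRS1, the insulin receptor substrate, at -2.63 (lower in 10 of 10 pairs) and SESN2 at 1.95. Immediate early genes had 9 rises and 4 falls among 27 (JUNB at 1.49, NR4A1 at -2.13), and glucocorticoid response and metallothionein genes 7 rises and 2 falls among 18 (MT2A at 3.33, GLUL at -1.24). Senescence and p53 genes had 6 rises and 1 fall among 17 (CDKN1A at 3.01), heat shock and chaperone genes 8 rises and 3 falls among 19 (BAG3 at 0.91), and stress response and unfolded protein genes 4 rises and 0 falls among 21 (CHAC1 at 3.78). The remaining lists were inflammatory cytokines (2 rises and 2 falls among 12; TNFRSF12A at 2.61), complement (2 and 4 among 21; C4A at 1.59, not separable with certainty from its near-identical copy C4B), circadian clock (2 and 4 among 19; BHLHE41 at -1.54), hypoxia and angiogenesis (3 and 3 among 18; EGLN3 at 1.35) and polyamine metabolism (3 and 2 among 14; SAT1 at 1.08). For the class IIa deacetylase, embryonic fibre, satellite cell, cell cycle and hypoxia lists the median and the mean of the log2 fold changes differed in sign, and none of these lists passed the camera test. In injured against healthy muscle the median, the mean and the direction of the camera test did not all have one sign for the cell cycle, lymphocyte (T and NK), TGF-beta, cytokine, hypoxia, polyamine and heat shock lists. In post-Sx against injured muscle this held for the class IIa deacetylase, embryonic fibre and satellite cell lists. The 4 lists whose call held with an estimated correlation were denervation response (adjusted p = 0.0427), glycolysis and glycogen, fibro-adipogenic progenitor and ribosome biogenesis, and fry called 20 of the 41.

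**Figure D2:**
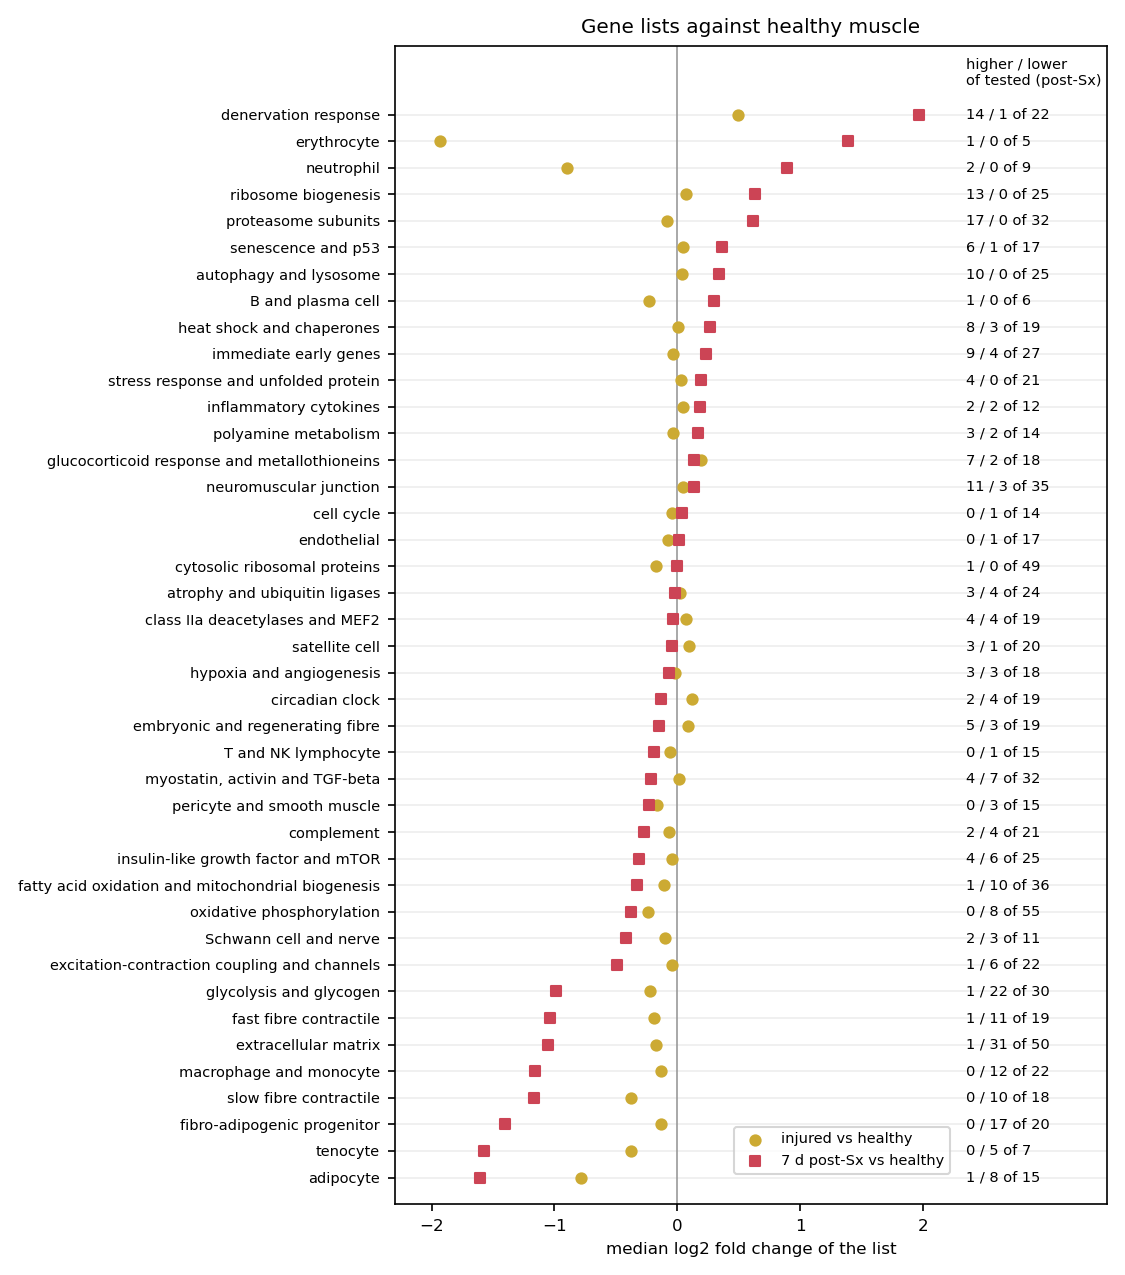
Median log2 fold change over the tested members of each of the 41 gene lists (horizontal axis), for injured (circles) and 7-day post-Sx (squares) against healthy muscle; the numbers at the right give members higher and lower post-Sx among those tested. The denervation response list has medians of 0.49 and 1.97, and the fibro-adipogenic progenitor list -0.13 and -1.40.

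Among all genes of at least 1 CPM that moved the same way in at least 75% of pairs, among the largest rises post-Sx were those of CHI3L1, a secreted chitinase-like protein (log2 fold change 6.07, SE 0.75, adjusted p 1.07e-06), the long non-coding RNA MIR503HG (5.18), the acute-phase genes SAA2 (4.96) and SAA1 (4.82), MYBPH (4.24), CHRNA1 and CHAC1 (3.78). SAA1 and SAA2 are near-identical copies, so that the division of reads between them is uncertain. The largest falls were those of COMP (-6.70, SE 1.11, adjusted p 6.55e-05), ACTN3, CA14 (-5.56), GAS2L2 (-5.29), SMCO1 (-5.15), COL22A1 (-5.03), TLCD3B (-4.93) and PRG4 (-4.79). SMCO1 went from 59.4 ± 15.8 CPM in healthy muscle (SD, n = 16) to 2.10 ± 2.69 CPM (SD, n = 10).

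The direct comparison of post-Sx with injured muscle tested whether the changes against the healthy limb differed between the 2 groups. HDAC4 was higher post-Sx than in the injured limb by 1.27 (SE 0.30, adjusted p 0.00416, 9 of 10 pairs), CHRNA1 by 2.90 (SE 0.38, adjusted p 8.43e-06, 10 of 10), MYOG by 2.01 (SE 0.27, adjusted p 8.34e-06, 10 of 10) and RUNX1 by 2.00 (SE 0.38, adjusted p 0.000577, 8 of 10). ACTN3 was lower by 5.06 on the log2 scale (value -5.06, SE 0.61, adjusted p 2.79e-06, 10 of 10 pairs lower). In the denervation list 13 of 22 members were higher and 1 lower (median 1.30; camera adjusted p 1.32e-08, adjusted p = 0.0512 with an estimated correlation), in glycolysis and glycogen 0 and 18 of 30 (median -0.66; 4.09e-11, adjusted p = 0.0646 with an estimated correlation), and in the fibro-adipogenic progenitor list 0 and 16 of 20 (median -1.42; 1.58e-13, adjusted p = 0.0404 with an estimated correlation). Of the 55 oxidative phosphorylation genes 0 passed in this comparison.

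In total 2346 genes differed between post-Sx and injured muscle, 1152 higher and 1194 lower (325 and 721 at least 2-fold). The test was edgeR's quasi-likelihood test in the joint fit of 42 libraries, with 10 pairs of these 2 groups. The joint fit also draws on the healthy libraries and on participants without a post-Sx library, so the count does not rest on the 10 pairs alone. With only the 10 participants with 3 libraries it was 1220. Among the largest rises were those of CHI3L1 (4.93), MIR503HG (3.85), HBA2 (3.61), CHGB, CHAC1 (3.33), SAA2 (3.31) and RRAD (3.26), the last from 207 ± 134 CPM (SD, n = 16) to 1705 ± 1037 CPM (SD, n = 10). The largest falls were those of COMP (-6.07), ACTN3, CA14 (-4.52), COL22A1 (-4.38), PRG4 (-4.36), SMCO1 (-4.13), GADL1 (-4.12) and FNDC1 (-4.08). The haemoglobin genes HBA1 and HBA2 are near-identical copies, and 4 of 5 erythrocyte markers were higher post-Sx than in the injured limb (median 3.33; camera adjusted p 0.000725, adjusted p = 0.178 with an estimated correlation). When only these 2 groups were fitted, 388 genes passed, and without the participant whose libraries are healthy 14, injured 14 and post-Sx 9 there were 1514. With upper-quartile scaling 34.2% of the calls were higher, against 49.1% (746 higher and 1434 lower).

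The injured and post-Sx changes against healthy muscle were compared over the 16252 genes. Their log2 fold changes had a correlation across genes of r = 0.552 (rho = 0.531; genes are not independent replicates), and 87.2% of the 3542 genes called post-Sx had the same sign in the injured limb. Both comparisons use the same healthy libraries, and with unchanged groups that share a healthy group, simulated by resampling the residuals of all libraries, the correlation of mean within-participant differences averaged 0.415, from -0.434 to 0.922 in 100 simulations, where the observed value was 0.546. The observed covariance was 0.109, against a simulated mean of 0.0417 (-0.0399 to 0.372). Between 6 participants without a post-Sx library and the 10 others, who share no library, r was 0.141 and rho 0.0725, and over all 64 swaps of the labels within the 6 participants r ranged from -0.290 to 0.290 (exact p 0.531). Between these participants 56.8% of the genes called post-Sx had the same sign in the injured limb, and 51.2% of all genes. The 6 participants include all 4 paired ones with library-name prefix A, and the 10 others all have prefix M. The fall from r = 0.552 can thus not be put down to the healthy libraries alone, since prefix and number of pairs changed too. With all participants the share of all genes with the same sign was 0.674, against a simulated mean of 0.645 (0.293 to 0.890). The number of genes called in both comparisons was 0, as was the number for independent lists, since 0 genes were called in the injured limb.

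Library names carry a prefix, A or M, and some a suffix b, whose meaning the labels do not give. The injury effect was compared between the 4 participants with prefix A and the 12 with prefix M: 0 of 14939 genes differed with edgeR's quasi-likelihood test, 823 had an unadjusted p under 0.05, and the smallest adjusted p was 0.689. HDAC4 had a log2 fold change for injury of 0.89 (SE 0.29) with prefix A and 0.96 (SE 0.31) with prefix M, but 1.76 (SE 0.29) in the 3 pairs with suffix b and 0.71 (SE 0.28) in the 13 without. Post-Sx against injured, it stood at 0.13 in the 2 pairs with suffix b (SE 0.32, adjusted p 0.927 with edgeR) and 1.57 in the 8 without (SE 0.33, adjusted p 0.00295 with edgeR). All post-Sx libraries have prefix M; within it 3215 genes were called against healthy and 1512 against injured muscle. Without the suffix b there were 2912 and 1784 calls (8 pairs), and within it 184 and 6 (2 pairs). For injured against healthy, prefix A, prefix M and the libraries without suffix b each gave 0 calls, and the 3 pairs with suffix b gave 5.

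Libraries differed in the number of genes detected. The first principal component of log2 CPM held 38.2% of the variance and followed the number of genes with a count above 0 over the 43 libraries (r = -0.896, rho = -0.770, permutation p 1e-05 for each, the smallest that 100000 permutations give; r = -0.785 without the 2 farthest libraries). Within healthy, injured and post-Sx libraries r was -0.712, -0.932 and -0.969. The lowest numbers of genes were in injured 12 (13616), post-Sx 1 (17212), post-Sx 7 (18481) and injured 11 (19042). The mean difference in genes detected between post-Sx and healthy muscle was -511 (SD 1923, n = 10 pairs, 5 of 10 higher; exact sign-flip p 0.576, both directions, adjusted p 0.960 over 15 tests). The 10 most abundant genes took 21.4 ± 3.17% of counts post-Sx (SD, n = 10) and 26.4 ± 2.14% in healthy muscle (SD, n = 17), a difference of -4.92 percentage points within pairs (exact sign-flip p 0.00977, adjusted p 0.0732). Without the 2 libraries with the fewest genes, 5029 genes were called post-Sx against healthy (3390 of the 3542 among them) and 3424 against injured muscle; with the number of genes detected as a covariate the counts were 5031 (3537 of the 3542 among them) and 3836.

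**Figure D3:**
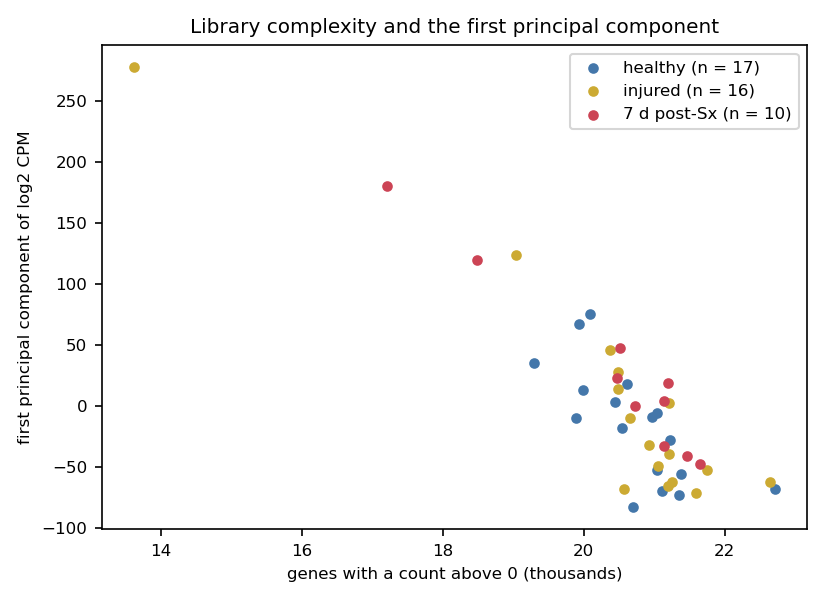
First principal component of log2 CPM (vertical axis) against the number of genes with a count above 0 (horizontal axis, in units of 1000), for healthy (n = 17), injured (n = 16) and 7-day post-Sx (n = 10) libraries; each point is a library. The libraries with the fewest genes, injured 12 and post-Sx 1, have the highest values on the component, and r over all 43 libraries is -0.896.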

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

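The tests with the number of genes detected as a covariate on the post-Sx calls and on the connective tissue markers, the comparison of marker lists with endothelium, and the label swaps without the 2 libraries with the fewest genes were chosen after the results they bear on were seen.

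HDAC5 in post-Sx 1 had a log2 CPM of 9.06, against 5.77 to 7.12 in the other 9 libraries of the group, and stood out as a sample far from the others. This library has the second lowest number of genes detected. In all, 39 series of values were tested in this way, for which chance gives 1.95 such samples, and no explanation was tested for the HDAC5 value. Outside these flags, GADD45A had a log2 CPM of -3.46 in 1 injured library, against 2.56 to 6.59 in the other injured libraries.

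The change against healthy muscle differed between injured and post-Sx muscle for 2346 genes, by a direct test of post-Sx against injured. With labels swapped within participants 1 of 22 splits, the real one, called as many, the lowest share that 22 splits can give. Since other splits came near that count, the swaps do not exclude chance for the bulk of these genes. The highest other split called 2220 genes and swapped 2 of 10 pairs, 1 that swapped 5 pairs called 1888, those that swapped 3 called at most 87, and 17 called 0. Without the 2 libraries with the fewest genes the real labels called 3424 genes (1 of 22 splits) and the highest other split 1632, so these libraries do not account for the high counts of other splits. The cause of these high counts was not found, and with only the 2 groups in the fit 388 genes were called.

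For post-Sx against healthy muscle, 3542 genes were called with the real labels (1 of 22 splits as large) and at most 1 with other labels. With each library's trend over transcript length removed, a share of 0.912 of the called genes stayed called in the same direction, 0.941 with the trend over GC content removed and 0.999 with genes detected as a covariate, which argues against these as the main cause of the calls. Sequencing batch stays open, since the post-Sx libraries may have been sequenced apart from the others, and for all these genes batch and group cannot be told apart. The biological difference that the design names, 7 days after Sx, also stays open.

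Post-Sx, 17 of 20 fibro-adipogenic and 12 of 22 macrophage markers fell (camera adjusted p 0.0427 and 0.299 with an estimated correlation, so that only the former list passed this test). Within participants the macrophage list had a mean log2 difference of -0.948, lower in 9 of 10 pairs (exact sign-flip p 0.00586, adjusted p 0.0133 over the lists). A larger share of muscle fibre RNA would lower the markers of every other cell type alike, but the fibro-adipogenic list fell further than the endothelial list by a mean log2 difference of -1.39 (SD 0.527, below 0 in 10 of 10 pairs, exact sign-flip p 0.00195). For the macrophage list this difference was -0.971 (SD 0.701, below 0 in 9 of 10 pairs, exact sign-flip p 0.00586). With genes detected as a covariate the median of the fibro-adipogenic list was -1.29, which argues against library complexity. A larger share of muscle fibre RNA as part of the cause, a loss of these cells and lower expression within them stay open. So do sampling of another part of the muscle and sequencing batch.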

How the results depend on the processing

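The fits without libraries of few genes or without both their participants, with genes detected, the first principal component or the TMM factor as a covariate, with sample quality weights, and with limma-voom and a replicate block were chosen after the results were seen.

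Injured against healthy muscle gave 0 genes with edgeR (740 at an unadjusted p under 0.05), 8 with DESeq2 and 1 with sample quality weights. Post-Sx against healthy gave 3542, and 6264 with sample quality weights, 5653 with the first principal component and 7394 with the TMM factor as a covariate. Leaving out 1 participant at a time gave 2822 to 4144. Post-Sx against injured gave 2346, but 388 with only the 2 groups compared, 1220 with only the 10 participants with 3 libraries and 1512 without the prefix A participants. It gave 3525 without the 4 libraries of fewest genes, 3836 with genes detected, 4316 with the first principal component and 5766 with the TMM factor as a covariate, and 5519 with sample quality weights. Leaving out 1 participant at a time gave 1514 (without healthy 14, injured 14 and post-Sx 9) to 3008. The cause was not tested. The correlation of the 2 sets of changes went from 0.552 to 0.141 in participants who share no library, where only 1 of the 2 sets holds prefix A.

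With no replicate block the pairing was ignored, and 0, 3636 and 2249 genes were called in the 3 comparisons. Of the 3542 genes 2970 were called in that fit too, and 1866 of the 2346. No count of called genes moved by over 1.5 times without the block. Of 145 named genes called post-Sx against healthy 121 passed in every setting, and of 142 against injured 63, with 0 changes of sign. HDAC4 passed in 36 of 36 settings against healthy (1.79 to 2.42) and 35 of 36 against injured (1.03 to 1.57).

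Changes of sign were found for 6 genes not called in the comparison concerned, and the cause was not tested. In injured against healthy, MUSK was at -0.057 with a random effect and -0.071 with quality weights (-0.079 to 0.26 leaving out 1 participant). FBXO32, TRIM63 and IGHM were at 0.033, 0.047 and 0.34 with no replicate block, and at 0.10, 0.082 and 0.43 with no replicate block and without the 2 low libraries. FBXO32 and TRIM63 were at 0.13 and 0.19 in the 10 participants, TRIM63 at 0.047 without prefix A, and FBXO32 at 0.096 without the 4 low libraries and 0.0076 without both participants (-0.15 to 0.045 leaving out 1).

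In post-Sx against healthy, HDAC5 was at 0.081 with no replicate block and 0.32 with the TMM covariate. CHRNE was at 0.15 without suffix b, 0.039 with weights and 0.010 with limma-voom (-0.46 to 0.011 leaving out 1). FBXO32 was at 0.13 with no replicate block, 0.0082 with a random effect, 0.043 in the 10 participants, 0.068 and 0.19 without 2 and 4 libraries, 0.040 with weights, 0.069 with the first component, 0.15 without both participants and 0.18 with no replicate block and without 2 libraries (-0.18 to 0.084 leaving out 1). TRIM63 was at -0.028 with DESeq2 and with RLE, -0.057 with upper quartile, -0.0055 with no filter, -0.21 and -0.057 without 2 and 4 libraries, -0.067 with genes detected, -0.13 with weights, -0.21 with the first component, -0.12 without both participants and -0.10 with limma-voom (-0.21 to 0.11 leaving out 1).

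In post-Sx against injured, HDAC5 and FBXO32 were at -0.0074 and -0.038 with DESeq2, -0.0072 and -0.038 with RLE, -0.045 and -0.069 with upper quartile, -0.042 and -0.12 with only the 2 groups, and -0.021 and -0.012 without prefix A. HDAC5 was at -0.29 and -0.25 without 2 and 4 libraries, -0.057 with weights, -0.16 with the first component, -0.26 without both participants and -0.19 with no replicate block and without 2 libraries (-0.29 to 0.15 leaving out 1). FBXO32 was at -0.086 in the 10 participants and -0.13 with the TMM covariate (-0.13 to 0.17 leaving out 1). TRIM63 was at -0.073 with only the 2 groups, -0.020 in the 10 participants, and -0.064 and -0.052 without 2 and 4 libraries (-0.046 to 0.34 leaving out 1).

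Libraries held a median of 19657987 counts. Simulated changes of 1.5-fold were recovered in 25.8% of cases in the first comparison, 5.97% in the second and 4.62% in the third. Each simulation changed only 200 genes, so these shares do not carry over to the post-Sx comparisons, where 3542 and 2346 genes were called. Of these 2836 and 1842 changed at least 1.5-fold, so smaller changes were called too. For injured against healthy muscle, with 0 genes called, smaller changes may lie below detection. All alternatives set in advance were run.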

Other observations

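The test of the denervation list within participants, the fit with sample quality weights, the use of genes detected as a covariate, the swaps of labels among 6 participants and the final form of the simulation were chosen after results had been seen.

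For the injured limb 0 genes were called with the real labels by edgeR (740 at an unadjusted p under 0.05, 8 with DESeq2 and 1 with sample quality weights), and 22 of 22 splits gave as many (highest other 0). The injury effect by name prefix gave 0 genes by edgeR (823 at an unadjusted p under 0.05), also with RLE scaling and with no replicate block, and 24 of 24 splits gave as many (highest other 0). With a real count of 0 every split gives as many, so these splits cannot exclude chance and show nothing further.

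A response of the denervation list in the injured limb is a hypothesis from these data. The mean of its members' differences within participants was 0.448 (SD 0.757, above 0 in 10 of 16 participants, exact sign-flip p 0.0331, adjusted p 0.316 over 41 lists), which may reflect a shift of the list as a whole but fails the adjustment. The list does not stand out, since glycolysis and glycogen (-0.333, exact sign-flip p 0.00446) and erythrocyte markers (-1.74, exact sign-flip p 0.0175) had smaller p. Neutrophil markers, fatty acid oxidation and mitochondrial biogenesis, and endothelial markers also had p under 0.05 (exact sign-flip p 0.0377, 0.0461 and 0.0463). HDAC4 moving with the rest of the list across participants was not settled: r was 0.311 (permutation p 0.24) and rho 0.276 (permutation p 0.30), with r = 0.325 without the 2 farthest participants. Of 1000 random gene lists over the same participants 6 had an r as large (median -0.232). These lists sample genes and not participants, so they do not settle the question. Given genes detected, r was 0.382.

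The similar direction of the injured and post-Sx changes may come from the shared healthy libraries. Between participants who share no library the correlation across genes was 0.141, which lies between the bounds set in advance. The observed covariance lay within the range of a simulation that was revised after its first outcome was seen, so that shared libraries and a shared effect cannot be told apart. Name prefix also differs between the 2 sets of participants, so the correlation between them does not isolate the shared libraries. With genes detected as a covariate the correlation between these participants was 0.282, the highest of the 64 swaps of labels within the 6 participants without a post-Sx library (highest other 0.260). Its exact p of 0.0312 is the lowest that these swaps can give. This argues against library complexity as the whole cause only if there is a similarity to explain. Without the covariate the exact p of the swaps was 0.531, so a similarity between these participants was not established.

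The healthy library without a second library from its participant entered no paired test. Of 15 core genes in the table, it lay above all other healthy libraries for 0 and below them for 1.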
